A study of Mus musculus with 2 samples.

How the data were processed

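Total RNA from mouse embryonic fibroblasts of the NMRI outbred stock was measured on Illumina bead arrays, on which each probe is carried by many randomly placed beads and read as fluorescence in 1 colour (Cy3). There were 2 samples, a control and a culture given FGF2, with 1 array each. Groups and the FGF2 dose were taken from the sample titles, descriptions and protocols. Per the labels' protocols, the RNA was column-purified with DNA digestion, and 300 ng was amplified by a linear method with 6 h of in vitro transcription. The array signals were processed with BeadStudio version 1.0, per the submitters' processing notes. Normalization in that program is not given in the sources used here.

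For each of 24044 probes the deposited per-sample tables give an average bead intensity, a bead standard deviation in the same intensity unit, and a detection score between 0 and 1. The detection score, per the file headers, is named only as detection; a score of at least 0.99 was taken as detected. The number of beads per probe is not given in the sources used here, so it stays open whether the bead standard deviation is a spread of beads or an error of their mean, and it was used as deposited. It measures variation within an array only and leaves out variation between cultures. The authors' value table holds a further intensity per probe whose method is not given in the sources used here. Set against the array signals, its control column equals the signal less 135.42 (between 135.37 and 135.5). Its FGF2 column follows a straight line with slope 1.278 and intercept −169.4, with residuals of at most 0.0936% of the value, which amounts to a background of 132.6 and a rescaling. Both columns are empty for probes with a detection score under 0.99, and their medians are 262.1 for control and 276.8 for FGF2. The scale of that table is therefore linear and not centred per gene. What sets its scaling factor is unknown.

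The array tables hold no gene names. Identifiers of the form scl0 or scl00 followed by a number were named by matching that number to the NCBI gene numbers of the RefSeq table for assembly GRCm38.p6, a reading of the identifiers that was tested on them. Of 9523 identifiers with 1 or 2 leading zeros, 8884 (93.3%) held a listed gene number, against 48.6% after adding 1 to each number and 36.1% after adding 50. Among 3167 numbers in sparsely filled ranges, 91.3% were listed, against 19.8% after adding 50. Of 10988 identifiers without a leading zero, 10.3% were listed and 10.1% after adding 50, as many as by chance, and these were left unnamed, as were 3273 with 3 or more leading zeros. Another 9 probes were named through an accession. For 219 genes with 2 named probes detected on both arrays, the log2 ratios of the 2 probes correlated with r = 0.859 across genes. Genes are not independent replicates, and the highest r in 10000 random pairings was 0.293. Probes sharing any other kind of number for a transcript would also correlate, so this value does not bear on whether the names are right. In all, 8893 probes (37.0%) were named, for 7413 genes, of which 6125 had 1 probe and 1288 several. The remaining 15151 probes have no gene name here, so a gene without a named probe is unmeasured here, not absent from the array. The names rest on this reading of the identifiers and not on a probe annotation.

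The 90th percentiles of the signals, 649.8 and 548.4, differed between the arrays by more than the 5% set beforehand, while the 10th percentiles, 118.3 and 116.4, did not. The deposited signals were therefore quantile normalized. Values under a floor were then set to it, and log2 was taken. The floor was the lowest normalized signal among detected probes, 188.45 on the control array and 191.7 on the FGF2 array. A probe counted if it was detected on at least 1 array. The probe with the highest mean deposited signal over both arrays stood for its gene. A gene was left out if that probe did not count, even where a dimmer probe did, so counts of detected genes refer to the brightest probe. For a gene detected on 1 array only, the ratio is a bound, given as at least N-fold, of the measured side over the higher of the floor and the dim probe's own normalized signal. List medians take a bound at its value. No background was subtracted in these values, which understates the fold change of dim genes. Because each group had 1 array, no p-value was computed for a difference between the groups. The differences have no replicate check, and genes are counted by size, at 2-fold or more. A share of reassignments, given for glycolysis genes below, compares sets of genes and not the groups. Errors given as ± are the combined bead errors of the 2 arrays on the log2 scale, with a median of 0.075 and a maximum of 0.12.

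Before the data were examined, 31 gene lists with 728 distinct members were fixed, of which 293 have a named probe and 180 were detected. For lists with at least 3 detected members, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean signal in 20 bins. Lists under the 2.5 or over the 97.5 percentile are called lower or higher, as a description of these 2 arrays. Of 25 such lists, 1.25 would lie outside by chance if the members of a list varied independently. Several lists share members, and members of a list may vary together between any 2 cultures, so more lists could lie outside without an effect of FGF2. Genes were named by a rule fixed at the same time. It took a preset set (Inhba, Tgfb1, Bmp4, Grem1, Fst, Fgf2, Fgfr1, Dusp6, Spry4, Acta2, Tagln, Cdkn1a and Mki67) and the 8 genes with the largest ratio each way among those detected on both arrays. It added up to 2 members each way per list among those changed at least 2-fold, and the highest and lowest reference gene. The rule named 44 measured genes, of which 1 is not reported here. Other list members are named as examples that were chosen after their values were seen.

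The alternatives were the deposited signals without scaling, median scaling, loess (span 0.3), normexp background correction with an offset of 50, the offset without a floor, no floor, stricter and looser detection filters (including a score of 0.95), the mean of a gene's probes, unmatched random lists, fold thresholds of 1.5 and 3, a requirement of 3 bead errors and the authors' value table. In 1 simulated comparison of 2930 genes, with signals and noise built from the control array alone, none of 2739 unchanged genes was called at 2-fold. That simulation holds noise within arrays only and no variation between cultures, so it says nothing of false calls between cultures. Of genes simulated at 2.5-fold, 14 of 27 raised and 6 of 19 lowered genes were called. At 4-fold, 26 of 27 raised and 14 of 22 lowered genes were called, and at 8-fold, 23 of 23 raised and 12 of 25 lowered genes were called. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and R 4.3.3 with limma 3.58.1, were used. The figures were drawn with matplotlib 3.10.9.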

Results

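The data describe mouse embryonic fibroblasts that had been inactivated with mitomycin C, a DNA crosslinker that stops division, as is done for feeder layers of human embryonic stem cells. Per the labels' protocols, the cells were replated on gelatine at 55000 cells per square centimetre, moved the next day to a serum replacement medium for human embryonic stem cells, and harvested after 24 h. The 2 cultures differed by FGF2, a fibroblast growth factor, which was left out of the control and given at 40 ng/ml to the other. Each was measured on 1 array of 24044 probes, so there are no replicates and the number of arrays limits the precision of every value. On the control array 7599 probes (31.6%) were detected, with a median signal of 152 and an upper quartile of 243.9. On the FGF2 array 7424 probes (30.9%) were detected, with a median of 147.5 and an upper quartile of 217.8. In all, 6915 probes were detected on both.

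The comparison asks which transcripts of inactivated fibroblasts differ after 24 h with FGF2. Among genes detected on both arrays, the largest reduction was that of Ptn (scl0019242.2_183-S), which encodes the secreted growth factor pleiotrophin, at 27.7-fold lower (log2 ratio −4.79 ± 0.077). Transcripts of other secreted proteins followed. Sfrp1, a Wnt antagonist, was 9.22-fold lower (−3.20 ± 0.071), Ccdc80, a matrix-associated protein, 9.08-fold lower (−3.18 ± 0.068), and Serpina3n, a serine protease inhibitor, 8.04-fold lower (−3.01 ± 0.096). The largest increase was that of Errfi1 (scl074155.4_43-S), a feedback inhibitor of EGF receptor signalling, at 12.0-fold higher (3.58 ± 0.077). Gch1, which starts tetrahydrobiopterin synthesis, was 10.5-fold higher (3.39 ± 0.071), although its dimmer probe gave a log2 ratio of 0.95.

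Further genes of the 8 largest increases were the granzyme gene Gzme at 6.33-fold (2.66 ± 0.10), Ptgs1, which encodes cyclooxygenase 1, at 5.24-fold (2.39 ± 0.090), and Ccnd1, which encodes cyclin D1, at 4.68-fold (2.23 ± 0.056). The lowest of 3 Ccnd1 probes gave 1.43, and the dimmer of 2 Gzme probes 2.39. Spp1 (osteopontin) was 3.80-fold higher, Ptges (prostaglandin E synthase) 3.73-fold and Sat1, which acetylates spermidine and spermine, 3.63-fold. The 8 largest reductions also held Timp3 at 7.20-fold, Col8a1 at 5.57-fold, the cytochrome P450 gene Cyp1b1 at 5.38-fold and Pdgfrl at 5.20-fold lower. The bead errors of these ratios were far below the differences, but they leave out variation between cultures and are relative to signals that include background. Several dim sides were little above the lowest detected signals, 194.6 in control and 184.9 with FGF2. In control these were Ptgs1 (207.7), Ptges (224.2) and Gzme (231.5). With FGF2 they were Pdgfrl (208.9), Ptn (210.9) and Serpina3n (231.8). The size of these folds depends on how background is treated.

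Of 3007 named genes detected on at least 1 array, 44 were at least 2-fold higher with FGF2 and 78 at least 2-fold lower, so 36.1% of the changed genes were higher. At 4-fold or more there were 6 higher and 18 lower genes. Of the 2-fold differences, 6 of the higher and 15 of the lower are bounds. Another 2644 genes (87.9%) lay within 1.5-fold, the median log2 ratio was 0.028, and log2 signals correlated with r = 0.948 across the 2641 genes detected on both arrays, which are not independent replicates. The split depended on scaling. Signals as deposited gave 28 higher and 113 lower genes (19.9% higher), with a median log2 ratio of −0.14. The authors' value table gave 138 and 158 (46.6% higher), with a median of 0.12. That table differs by a subtracted background and by the scaling of the FGF2 array. In it, Ptn was 62.8-fold lower, and Ptgs1 14.4-fold, Gzme 15.2-fold, Gch1 18.0-fold and Ptges 8.55-fold higher. Errfi1, at 17.7-fold higher, came under Gch1 there. Serpina3n, at 15.9-fold lower, passed Sfrp1 at 14.9-fold and Ccdc80 at 12.8-fold lower. The order of the largest differences therefore depended on the values used.

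**Figure D1:**
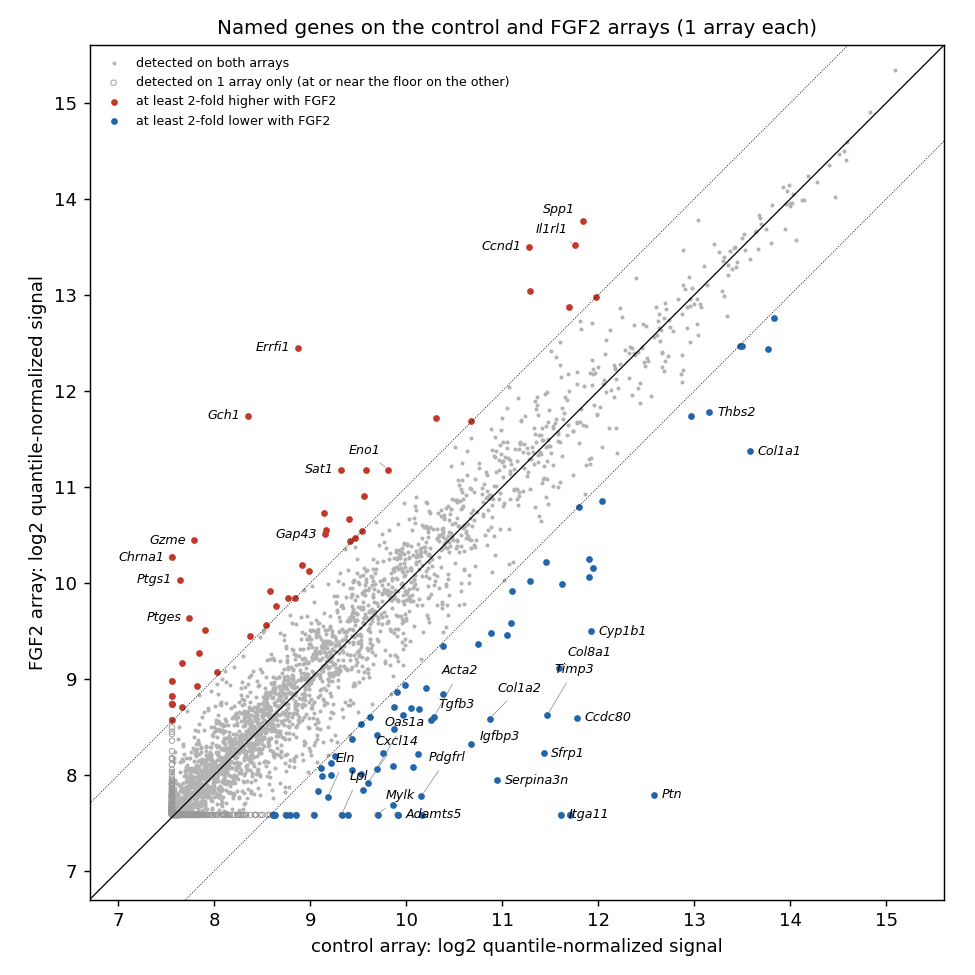
Log2 quantile-normalized signal of each named gene detected on at least 1 array, control on the horizontal axis and FGF2 on the vertical axis, with 1 array each. Dotted lines mark 2-fold, open circles are genes under 2-fold detected on 1 array only, and labels mark larger differences among genes named by rule; 78 genes lie at least 2-fold below the diagonal and 44 at least 2-fold above it.

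Collagen transcripts were lower with FGF2. Of 8 detected genes in the list of fibrillar and basement membrane collagens, 7 were at least 2-fold lower and none was higher. Col8a1 was at −2.48 ± 0.083, and Col1a2 and Col1a1, the chains of type I collagen, were 4.87-fold and 4.62-fold lower (−2.28 ± 0.094 and −2.21 ± 0.093). The raw Col1a1 signal was 12828 in control and 2494 with FGF2. Col3a1 was at −1.79, Col5a1 at −1.33 and Col6a1 at −1.01, Col4a5 was at least 2.03-fold lower, and Col6a3 had the smallest reduction at −0.69. The list's median was −1.56, below each of 10000 random lists matched on signal (percentile 0).

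Other matrix genes were also lower as a list. Of 14 detected genes for other extracellular matrix and matrix processing, 6 were at least 2-fold lower and 1 was higher (median −0.86, percentile 0). Eln (elastin) was 2.66-fold lower (−1.41 ± 0.091), Thbs2 (thrombospondin 2) 2.60-fold lower (−1.38 ± 0.059), and the collagen chaperone gene Serpinh1 was at −1.08. The member that was higher was Spp1, at 1.93 ± 0.079. Of 10 matrix proteases and their inhibitors, 5 were at least 2-fold lower (median −0.65, percentile 0). Over all 13 with a named probe, detected or not, the median was 0.0059, within the random lists (percentile 9.87). The metalloproteinase inhibitor Timp3 was at −2.85 ± 0.072, with −0.91 from its dimmer probe. The aggrecanase Adamts5 was at least 5.02-fold lower, Adamts2 was at −1.53 and Adam12 at −1.52, while Mmp12 was at least 1.86-fold higher. Among 6 fibroblast genes 3 were at least 2-fold lower (median −0.65, percentile 0.24). These were Col1a1, Col1a2 and Fbln1, and without the collagens the list's median was 0.019, within the random lists (percentile 52.2, an alternative chosen after the data were seen).

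Contractile genes were divided. Acta2, which encodes smooth muscle actin, was 3.21-fold lower (−1.68 ± 0.066). Mylk (myosin light chain kinase) was at least 4.34-fold lower, and the collagen receptor subunit Itga11 at least 16.3-fold lower, with −0.078 from a dimmer Itga11 probe. The other 8 of 11 detected genes lay between −0.67 (Cnn3) and 0.59 (Zyx). The list's median of −0.0019 lay within the random lists (percentile 41.2).

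TGF-beta superfamily ligands were lower as a list. Tgfb3 was 3.21-fold lower (−1.68 ± 0.060) and Tgfb2 2.38-fold lower (−1.25 ± 0.055). None of the 6 detected members of the list was 2-fold higher (median −0.50, percentile 0.37). The list's median lies between Gdf10 (−0.65) and Bmp1 (−0.35), and Bmp1 encodes a procollagen protease, not a ligand of this family. Over all 13 members with a named probe, detected or not, the median was 0.025. Among 6 antagonists and binding proteins, Ltbp2, which binds to the matrix, was 2.03-fold lower (−1.02 ± 0.055), Fst (follistatin, which binds activin) was at −0.077 ± 0.069 and Ltbp1 was at 0.80. Ltbp2 was under 2-fold with median scaling (−0.94) and in the authors' value table (−0.85). The median of the antagonists was −0.088 (percentile 22.7). None of 6 receptors and Smads differed 2-fold (median −0.14, percentile 8.97). Among 3 Smad target genes, Ltbp2 was lower, Id3 was at 0.87, and the median was 0.36 (percentile 94.4). Inhba, Tgfb1, Bmp4 and Grem1 have no named probe here, so the ratio of Inhba to Bmp4, chosen in advance, could not be computed.

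Genes known as feedback regulators of ERK signalling and FGF targets were higher as 1 list. Of 6 detected, 3 were at least 2-fold higher (median 1.08, percentile 100). These were Errfi1, Ccnd1 and the ETS factor gene Etv1, which was 3.03-fold higher (1.60 ± 0.066) on its brightest probe and at 0.20 on another. Spred1 was at least 1.46-fold higher, Dusp7 was at 0.026 and Flrt3 at −0.43. The list's median lies between the bound of Spred1 and the value of Etv1. Over all 8 genes of the list with a named probe, detected or not, the median was 0.29 (percentile 99.84). Fgf2, Dusp6 and Spry4 have no named probe here. Of 5 FGF ligands, receptors and cofactors, none differed 2-fold (median −0.0030, percentile 35.5), and the Fgfr1 probe was not well above background, with signals of 174.7 and 154.7. Of 6 immediate early and AP-1 genes none differed 2-fold (median 0.26, percentile 94.8).

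Growth factor genes differed in opposite directions. Beside Ptn, Igfbp3, which encodes an IGF binding protein, was 5.12-fold lower (−2.36 ± 0.055), and Pdgfa, the A chain of PDGF, was 2.40-fold higher (1.26 ± 0.081). The 12 detected genes of the list had a median of −0.0099 (percentile 28.0). Of 6 Wnt pathway genes, Sfrp1 was lower and the ligand gene Wnt5a was 2.04-fold higher (1.03 ± 0.068), with a median of −0.031 (percentile 28.6). Wnt5a was under 2-fold with signals as deposited (0.79), with loess (0.998) and with an offset and no floor (0.94).

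Cyclin D1 aside, which is counted with the ERK targets, none of the 11 detected genes in the list of cell division genes differed 1.5-fold. They lay between −0.20 (Tk1) and 0.22 (Cenpa) around a median of 0.0048 (percentile 38.9). Mki67, a marker of cycling cells, was at 0.011 ± 0.077 on the 1 of its 2 probes that was detected. Its deposited signals, 248.1 in control and 223.3 with FGF2, were little above the lowest detected signals of 194.6 and 184.9. A difference at that level is understated without background subtraction. The p53 target Cdkn1a, which encodes a cell cycle inhibitor, was at −0.20 ± 0.065, and the 5 detected p53 targets had a median of −0.17 (percentile 10.6).

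Genes of glycolysis were higher. Of 11 detected glycolysis and hypoxia genes, 4 were at least 2-fold higher and none was 1.5-fold lower (median 0.64, percentile 100). With signals as deposited the list's median was 0.38 (percentile 99.99). Eno1 (enolase) was 2.59-fold higher (1.37 ± 0.078), Pkm (pyruvate kinase) 2.25-fold (1.17 ± 0.067; 0.98 with signals as deposited), and Aldoa (aldolase) was at 1.02. Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors, was at least 2.02-fold higher. Cholesterol synthesis genes shifted by less. None of 11 reached 2-fold and 3 reached 1.5-fold, with Acat2 at 0.73 and Lss at 0.68 (median 0.43, percentile 99.99). Reference genes had a median of 0.28 over 12 genes (percentile 99.3), between −0.56 ± 0.066 for B2m and 0.76 ± 0.069 for Pgk1. Without the glycolytic genes Gapdh and Pgk1 their median was 0.21, within the random lists (percentile 96.0). The 3 amino acid and ER stress genes had a median of −0.34 (percentile 6.21), with none at 2-fold.

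Interferon response genes were lower. Of 9 detected, 4 were at least 2-fold lower and 8 at least 1.5-fold lower (median −0.85, percentile 0.01). Oas1a, an antiviral enzyme, was 3.08-fold lower (−1.62 ± 0.072). Ifit3 was at least 2.41-fold lower on its brightest probe and at −0.16 on the least changed of 3, and Irf9 was at −1.03. Cytokine and chemokine genes had a median of 0.33 over 7 genes (percentile 99.7), but over the 5 detected on both arrays the median, 0.18, lay within the random lists (percentile 85.8). Il1rl1, which encodes the IL-33 receptor, was 3.39-fold higher (1.76 ± 0.073), and the chemokine gene Cxcl14 was 3.21-fold lower (−1.68 ± 0.084).

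**Figure D2:**
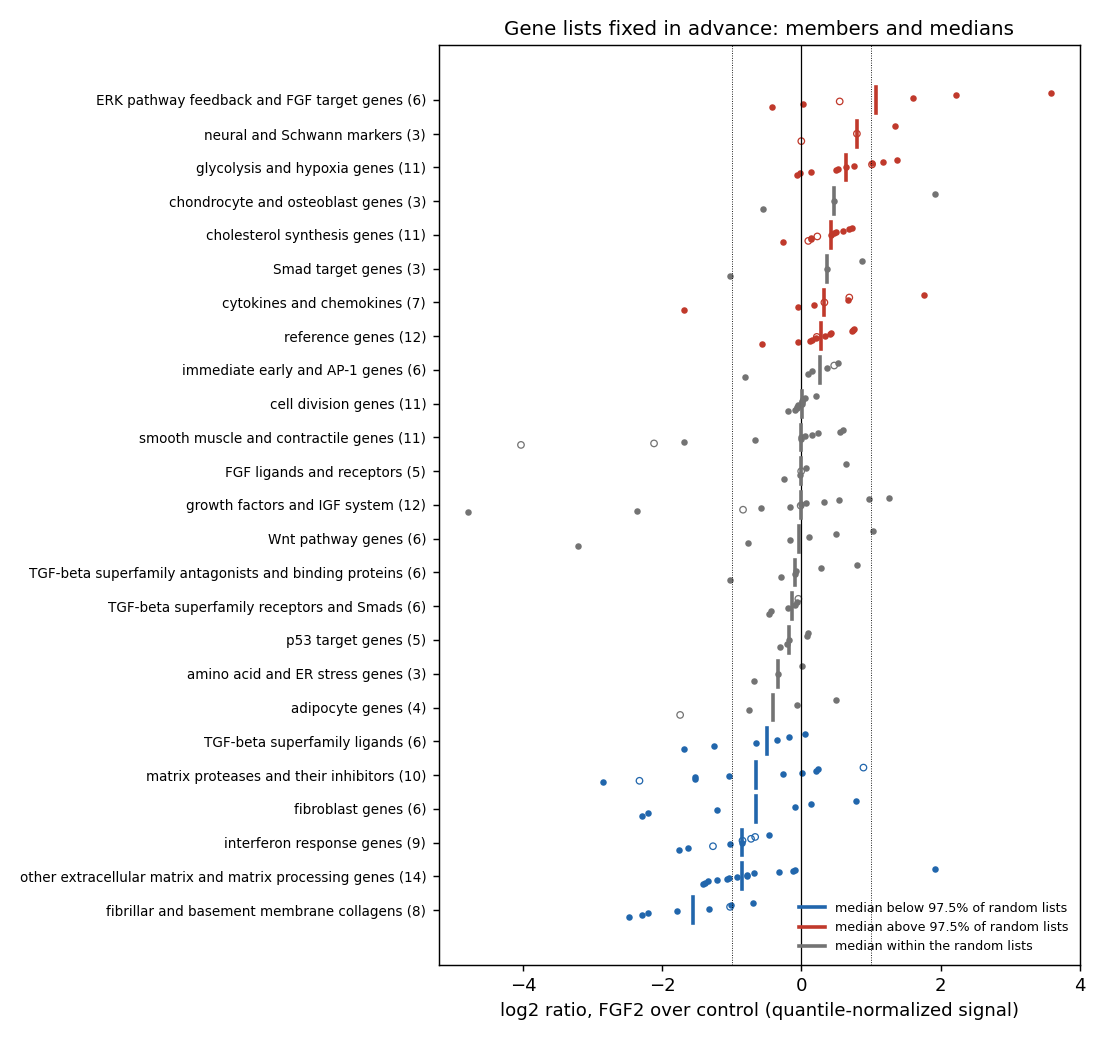
Log2 ratio of FGF2 over control for each detected member of the 25 gene lists with at least 3 detected members, 1 array per group; each point is a gene, open where it was detected on 1 array only, and bars mark medians. Colours mark the 6 lists whose median lay below and the 6 above the matched random lists. The collagens have the lowest median, −1.56, and the mixed list of ERK feedback and FGF target genes the highest, 1.08.

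Markers of other cell types were mostly near or under background. None of 4 endothelial and none of 7 pluripotent stem cell markers with a named probe was detected. Of 7 macrophage and leukocyte markers 2 were detected, Lyz2 at −0.58 and Cd53 at least 1.82-fold higher with FGF2. Of 5 epithelial markers 2 were detected, Krt18 at least 1.52-fold higher and Cldn4 at −0.0078. Of 3 erythroid markers Hbb-b1 was detected, on the FGF2 array only and at least 1.03-fold higher. The muscle acetylcholine receptor gene Chrna1, 1 of 2 skeletal muscle markers with a named probe, was at least 6.53-fold higher, while its other probe was not well above background. Of 3 detected neural and Schwann markers, Gap43, a growth cone protein, was 2.55-fold higher (1.35 ± 0.073). The intermediate filament gene Nes was at least 1.74-fold higher, and Tubb3 was detected in control only, near the floor. The list's median of 0.80 (percentile 99.8) is the bound of Nes. Over all 10 genes of that list with a named probe, detected or not, the median was 0.025. Of 4 adipocyte genes, the lipase gene Lpl was at least 3.35-fold lower, with a median of −0.41 (percentile 3.17). Of 3 chondrocyte and osteoblast genes Spp1 was higher, with a median of 0.47 (percentile 96.9).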

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

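The gene lists were fixed before the data were examined, but all tests of explanations were chosen after the results were seen. Probes without a gene name were not used in the gene comparisons and held differences as large as those of named genes. Of 4800 such probes detected on at least 1 array, 88 were at least 2-fold higher with FGF2 and 143 at least 2-fold lower. The largest increase, of probe scl37305.10.1_6-S, was 5.03 on the log2 scale (32.6-fold, signals 304.8 and 8728), above that of any named gene, and probe scl17359.5_60-S was 18.4-fold higher. Probe scl16279.4_434-S was at −4.26 and scl19952.5.1_24-S at −3.85. Which genes these probes measure was not determined here.

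The lower collagen genes were weighed against scaling, against a bias of bright probes and against another difference between the 2 cultures. A factor common to all genes cancels when the median of all genes is subtracted. The 4 scalings that act unequally on genes were quantile normalization (the main setting), loess, normexp followed by quantile normalization, and the authors' value table. Over these, the collagen median less the median of all genes lay between −1.59 and −2.05. The choice among these scalings therefore does not account for the lower collagen genes. Among the 10000 random lists matched on signal, already used to place the list, the lowest median was −0.95, above the collagen median of −1.56. This repeats that placement and is no separate test of a bias of bright probes. It shows only that random lists of similar signal did not reach the collagen median. With 1 array per group, a difference between the 2 cultures other than FGF2 cannot be told apart from an effect of FGF2. An effect of FGF2 on collagen expression therefore stays a hypothesis.

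The lower interferon response genes were weighed against scaling and against fewer leukocytes in the FGF2 culture. Less the median of all genes, their median lay between −0.88 and −1.71 over the same 4 scalings. The choice among these scalings therefore does not account for the pattern. Of 7 leukocyte markers with a named probe 2 were detected, Lyz2 with deposited signals of 374.8 and 220.2 and Cd53 with 176.7 and 318.7. These dim markers differed in opposite directions and are too few to decide, so fewer leukocytes with FGF2 remain a possible explanation, as does another difference between the cultures.

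The higher glycolysis genes were weighed against scaling and against an increase shared by housekeeping genes. Over these 4 scalings their median less that of all genes lay between 0.57 and 0.66, so the choice among them does not account for the increase. The shared member Pgk1 was left out, as was Gapdh, a glycolytic gene that is in the reference list only. The median of the 10 other genes of the glycolysis and hypoxia list was then 0.58 and that of 10 reference genes 0.21. Their difference was 0.37, and a share of 0.0726 of 100000 reassignments of these genes gave a difference as large in either direction. The genes are not independent replicates and the share leaves out variation between cultures, so it cannot decide the question. A rise shared by all housekeeping genes stays open. Another difference between the cultures could also account for the pattern.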

How the results depend on the processing

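Most alternatives were set before the data were examined; those leaving members out of the fibroblast and reference lists were chosen after seeing the data. No paired analysis was possible because each group had 1 array. Of 301 list medians under alternatives, 283 kept their call as lower, higher or within the random lists' bounds, and 473 of 479 values of named genes kept their side of 2-fold; the other 6 were of Wnt5a, Pkm and Ltbp2. Part of this agreement was fixed in advance. For a gene with 1 probe detected on both arrays, removing the floor, changing the detection filter or averaging probes returns the main value. Median scaling and signals as deposited differ by a common factor and gave the same list percentiles, so they are not separate checks. Some values without a call, such as those of Cdkn1a, Mki67 and cell division genes, changed sign under some alternatives. Collagens (−1.93 to −1.02), other matrix genes (−1.07 to −0.78) and interferon response genes (−1.60 to −0.83) kept their call under every alternative run. So did ERK feedback and FGF target genes (0.29 to 1.96), glycolysis (0.38 to 0.78) and cholesterol synthesis (0.19 to 0.68). The count of higher genes, 44, was 28 with signals as deposited, 78 with normexp, 138 with the authors' value table, 159 at 1.5-fold and 13 at 3-fold. The count of lower genes, 78, was 158 with that table, 204 at 1.5-fold and 33 at 3-fold. The chondrocyte and osteoblast list (3 genes) passed the upper bound with signals as deposited (0.31), median scaling (0.55), loess (0.45), normexp (0.73), genes on both arrays (0.47), the authors' table (1.11) and unmatched random lists (0.47). The adipocyte list (4 genes) passed the lower bound with normexp (−0.51), a detection score of 0.95 (−0.41), the authors' table (−0.47) and unmatched lists (−0.41). For these 2 lists the cause was not tested. Cytokines lost their call over genes on both arrays (0.18), with 5 genes left. Without a detection filter, TGF-beta ligands (0.025), matrix proteases (0.0059) and neural markers (0.025) lost their call, as members at the floor have a ratio of 0.025 by construction. Receptors and Smads gained a call there (−0.043; cause not tested). Fibroblast genes without collagens were at 0.019 and reference genes without glycolytic enzymes at 0.21. Signal over background limits dim genes, whose folds are understated without background subtraction.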

Other observations

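The 3 gene groups below were drawn up after some of their members were seen among the larger differences, so all tests of them were chosen after the result was seen and their percentiles are no independent evidence for the groups. Genes of the pentose phosphate pathway and targets of NRF2, a regulator of antioxidant genes, were higher with FGF2. Of 12 detected, 2 were at least 2-fold higher, 7 at least 1.5-fold and none lower (median 0.74, percentile 100 among matched random lists). Glrx (glutaredoxin) was at 1.58 on the log2 scale and Srxn1 (sulfiredoxin) at 1.34. The pathway's dehydrogenase gene Pgd was 1.96-fold and the transketolase gene Tkt 1.88-fold higher.

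Genes of class I antigen presentation and interferon-inducible GTPases were lower. Of 11 detected, 2 were at least 2-fold lower, 6 at least 1.5-fold lower and none higher (median −0.66, percentile 0). The median is the bound of Psmb8, which was detected in control only. The GTPase genes Irgm2 and Igtp were 3.97-fold and 3.24-fold lower, the class I heavy chain gene H2-K1 1.83-fold and the immunoproteasome gene Psmb10 1.99-fold lower. Of the detected members, B2m and Psmb8 are also in lists fixed in advance. Prostaglandin synthesis genes had a median of 0.69 over 7 genes (percentile 100). That median is the bound of Ptgs2, detected with FGF2 only and also a member of the cytokine list fixed in advance. Ptgs1, Ptges and the prostacyclin synthase gene Ptgis (2.16-fold) were at least 2-fold higher. Hpgd, which breaks prostaglandins down, was at least 1.54-fold lower.

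Among other large differences chosen after their values were seen, Ptx3, which encodes the soluble pattern recognition protein pentraxin 3, was at least 17.4-fold lower and the imprinted gene Mest at least 6.00-fold lower. Ass1 (argininosuccinate synthase) was 3.37-fold higher, and Smox (spermine oxidase) 2.69-fold higher beside Sat1 of the same polyamine pathway. A further granzyme gene, Gzmd, was at least 2.68-fold higher. Probes whose identifiers name immunoglobulin genes were almost all at background, with 1 of 203 detected on the control array and 4 on the FGF2 array, and none of 32 T cell receptor probes was detected.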
